A study of Mus musculus with 4 samples.

How the data were processed

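Total RNA from the CA1 hippocampus of mice was hybridised to Affymetrix MG-U74Av2 arrays, 1 per time, at 1, 2, 4 and 6 h after the last shock. Per the labels, the mice of all 4 samples received the same shocks, and the labels do not say how many animals went into a sample. The deposited table holds a linear intensity for each of 12488 probe sets on each array, all above 0. The deposited intensity values had already been brought to a common level, since the trimmed mean over all probe sets, leaving out 2% at each end, was 500.3 on each array. The software that made them, its version and any detection call are not given in the sources used here. A probe set is a group of short oligonucleotides that together read 1 transcript, and its signal depends on where they lie and on how well each binds.

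Probe sets were named from the platform's gene annotation. Of 12422 probe sets other than controls, 10833 had 1 gene symbol, 396 had several and 1193 had none. Of the 10833, 10817 were found by gene identifier in a RefSeq table and 0 symbols changed, while 16 were not found and kept their symbol. Probe sets with several or no symbols were counted and not named. The probe set with the highest mean intensity stood for a gene with several, which gave 8251 genes. Coordinates were not used.

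Each array was scaled so that its trimmed mean over the probe sets other than the 66 controls was the same, with factors from 0.999 to 1.001. Values below 100.8, the 40th percentile of all scaled values, were set to that floor, and log2 was taken. A value at the floor is a bound, so folds against it are given as at least so large. The intensities printed are the scaled values before the floor. Pairs of arrays were compared by the number of probe sets that differed by at least 2-fold among those above the floor on both. A probe set stood apart at 1 time when its value there was at least 1.5-fold above, or below, each of the other 3 arrays, among 6442 above the floor on all 4. One-way courses were those higher, or lower, at each later time with a total span of at least 2-fold. With 1 array per time single times cannot be tested against each other, and a linear trend over the hours was not fitted, so no test of significance was run.

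Lists of genes were fixed before the data were examined, 18 of processes and 13 of cell types. For each, the median log2 difference was taken over the members whose mean lay above the floor, for 6 pairs of times and for each time against the mean of the other 3. Its percentile was found among 10000 random lists of the same size, drawn within 10 bins of mean expression, which describes these arrays and not the conditions. The genes named were set beforehand by rank: the 10 farthest apart in each direction at each time, the 10 highest and lowest at 2, 4 and 6 h over 1 h, the 10 with the largest one-way spans, 3 bounds per time, up to 4 members of each list with the largest range, and a fixed set including Fos, Egr1, Nr4a1, Per1, Sgk1, Bdnf and Ttr. The text gives some of these. Btg2, Gadd45b, Klf9, Hsd11b1, Nsdhl and Folr1 lie outside that rule and were chosen after their values were seen.

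The alternatives fixed beforehand were the values as deposited, scaling to a common median, quantile normalization, floors at the 20th and 60th percentiles, other fold limits, plain probe sets alone, the mean over a gene's probe sets, the mean over members, and each other array left out. Added after the data were seen were the list medians without the 2 h, the 6 h or (for the glucocorticoid list) the 1 h array, the choroid plexus list without Ttr, the immediate early list without Fos, the glucocorticoid list without members shared with the immediate early list, and counts over probe sets with a mean intensity of at least 500. Scaling to a common median moved the median log2 difference of all probe sets between 2 h and 6 h by 0.11, and differences are given relative to the main scaling.

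The steps were tested on simulated arrays with known changes. The noise was independent and normal, sized from the 4 h and 6 h arrays, the pair that differed least. The robust SD of log2 differences was 0.26 for that pair and 0.285 to 0.32 for pairs with 2 h. Only probe sets with a mean above 2 times the floor were raised. The rates below may thus be better than on the real arrays. At 2 h, 80 of 100 probe sets raised 2-fold and 100 of 100 raised 4-fold were recovered as apart, and 22 of 6323 unchanged ones were called. A list of 30 genes raised by 0.3 was recovered with a median of 0.31, and 2 of 100 unchanged lists lay outside the middle 95%. The computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.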

Results

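The series follows gene expression in the CA1 region of the mouse hippocampus, a layer of pyramidal neurons needed for contextual memory, after foot shock. Young male C57BL/6J mice received 3 shocks of 0.5 mA, and total RNA was taken 1, 2, 4 or 6 h after the last of them. The labels call the condition shock alone and place the mice in the chamber 2 h before the shocks. Each time has 1 array, 4 in all, and each array reads 12488 probe sets. Untreated or context-only animals were not analysed here, so each value is set against the other times and not against a baseline. With no replicates, no p-value is given, and the number of arrays limits the precision of every value.

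Immediate early genes, the transcription factors and signalling genes that neurons induce within minutes to hours of activity, stood highest at 2 h. Fos read 310 intensity units at 1 h, 607 at 2 h, 161 at 4 h and 134 at 6 h. Egr1 read 1277, 2195, 1737 and 1299 at the same times, and Nr4a1, an orphan nuclear receptor, read 604, 997, 594 and 534. The growth regulator Btg2 was 1.44-fold higher at 2 h than at 1 h, and the stress gene Gadd45b read 425 at 1 h, 570 at 2 h, 454 at 4 h and 341 at 6 h. Nr4a2 differed in timing, at 805, 713, 483 and 388, and its second probe set had the same order, from 393 at 1 h to 217 at 6 h. Homer1, a dim member, went the other way, at 134, 93.5, 161 and 142, lowest at 2 h and below the floor there.

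Of the 38 immediate early genes on the array, 30 had a mean intensity above the floor of 100.8, and 21 of these 30 were highest at 2 h. The median of the list at 2 h was 0.37 (log2) above the mean of the other 3 times, at percentile 100 of 10000 random lists of equal size and like expression. In all, 24 members lay above the other times and 6 below, with 7 above by at least 1.5-fold. Without the 6 h array the median was 0.24. The array at 2 h was also the one with the highest ratios of 3' to 5' control probe sets, 2.70 for actin against 1.84, 1.79 and 1.74 at 1, 4 and 6 h, and 4.82 for Gapdh against 3.98, 3.85 and 3.24. The spike-in controls, transcripts added to each sample, had the same order over the arrays as the list. Relative to 1 h their geometric mean after scaling was 1.16 at 2 h, 0.94 at 4 h and 0.87 at 6 h. The list medians relative to the other times were 0.06, 0.37, −0.06 and −0.28 at 1, 2, 4 and 6 h. The second probe sets of Fos and Pim1 were below the floor on all 4 arrays, so a single probe set carries each of these genes, and the second of Egr1 was below it on 3 of 4.

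At 6 h the same list was lowest. Its median was −0.28 relative to the other times, at percentile 0.00, with 26 of 30 members below and 17 lowest at 6 h. Junb read 331 at 6 h against 491, 565 and 483 before, although its second probe set, at 97.7, 319, 189 and 227, was lowest at 1 h. Without the 2 h array the median was −0.17, at percentile 0.33. The control probe sets for 18S ribosomal RNA were also highest at 2 h and lowest at 6 h. From 1 to 6 h they read 3226, 4854, 2889 and 1872 at the 3' end, and 1386, 2007, 991 and 383 at the 5' end. The 6 h sample also held transthyretin and other choroid plexus transcripts, as described with the cell type markers.

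**Figure D1:**
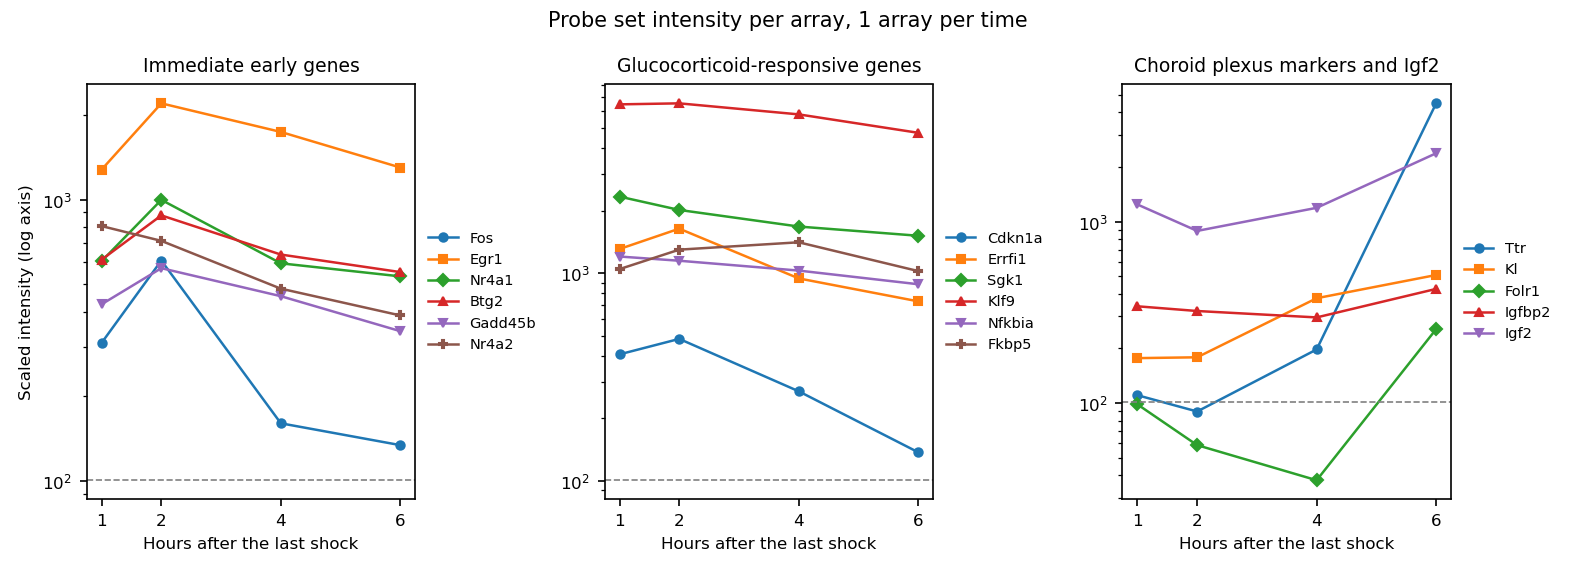
Scaled intensity (log axis) of named genes at 1, 2, 4 and 6 h after the last shock, 1 array per time, with the floor of 100.8 as a dashed line. Fos, Egr1, Nr4a1 and Btg2 are highest at 2 h, Cdkn1a is lowest at 6 h with 137, and Ttr stands at 4482 at 6 h.

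Genes known to respond to glucocorticoids, the adrenal hormones released under stress, were lower at 6 h than at 1 h. Sgk1, a kinase induced by corticosteroids, read 2334, 2013, 1675 and 1513 from 1 to 6 h, lower at each later time. Klf9, a transcription factor, read 6485, 6559, 5804 and 4732. Errfi1, an inhibitor of the epidermal growth factor receptor, was 1.79-fold lower at 6 h than at 1 h, although its second probe set, at 496 and 462, differed less. Cdkn1a, the cell cycle inhibitor p21, was 2.96-fold lower at 6 h than at 1 h, and its second probe set read 343, 347, 242 and 181. Nfkbia read 1202 at 1 h and 884 at 6 h, and its second probe set 763 and 418. Actb, an actin gene outside the list, was also lower at 6 h than at 1 h, at 3284 and 4224. Its second probe set read 2149 at 6 h and 2718 at 1 h. The 3' Gapdh control was lower too, at 34316 and 40063, and the 5' Gapdh control was higher, at 10584 and 10058.

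Of 25 measured members, 21 were lower at 6 h than at 1 h and 4 higher. The median difference was −0.24, at percentile 0.05 of random lists, and −0.16 after scaling to a common median. The list also stood above the other times at 1 h, with a median of 0.17 at percentile 99.8, and at 2 h, with 0.22 at percentile 99.99, where the actin ratio was 2.70. The spike-in controls were likewise higher at the earlier times, at 1, 1.16, 0.94 and 0.87 relative to 1 h. The 6 h array was also the one with Ttr at 4482. Hsd11b1, which regenerates active glucocorticoid, went the other way, at 520 at 1 h and 965, 941 and 967 later. Fkbp5, a chaperone of the glucocorticoid receptor, was highest at 4 h, at 1407, against 1045 at 1 h and 1023 at 6 h. The endothelial and mural cell markers had a median of −0.30 over the same interval, at percentile 3.74, and the astrocyte markers −0.12, at percentile 3.29. At 6 h over 2 h the astrocyte markers had a median of −0.17, at percentile 0.985 with 12 of 15 lower, and the glucocorticoid list −0.38.

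Cholesterol synthesis genes were higher at 1 h than at 2 h and 4 h. Fdps, the farnesyl diphosphate synthase, read 1188, 892, 746 and 758, and Nsdhl, a sterol dehydrogenase, read 530, 371, 375 and 404. Sqle, the squalene epoxidase, read 798 at 1 h, 565 at 2 h and 616 at 4 h, and was highest at 6 h with 1084. Over 17 measured genes the median was −0.24 at 2 h, at percentile 0.24, and −0.23 at 4 h, at percentile 0.42, each against 1 h, with 13 of 17 lower at each of these times. Both comparisons share the 1 h array, where the list stood 0.16 above the other times, at percentile 98.6. Against the other times it was not apart at 2 h, with −0.05 at percentile 22.4, and was lower at 4 h, with −0.18 at percentile 0.40. The actin ratio was 2.70 at 2 h and 1.79 at 4 h. At 6 h against 1 h the median was −0.13, at percentile 6.83.

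Transcripts of the choroid plexus, the epithelium that secretes cerebrospinal fluid, were higher at 6 h. Ttr, which encodes transthyretin and is the most abundant of them, read 111 at 1 h, 89.9 at 2 h, 198 at 4 h and 4482 at 6 h. Kl, which encodes klotho, read 177, 179, 378 and 508. Folr1, a folate receptor, read 255 at 6 h and was below the floor at the other times. Igf2, made in choroid plexus and meninges, read 2379 at 6 h against 1243, 888 and 1191, with its second probe set below the floor on all 4 arrays. The list of choroid plexus and ependymal markers had a median of 0.85 at 6 h over the other times, at percentile 100, from 6 measured members of 9 on the array, 5 of them above. That median was 0.55 without Ttr and 1.39 as a mean over members. Foxj1, a gene of ciliated ependymal cells, read 244 at 6 h against 296 at 1 h.

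Markers of CA1 pyramidal neurons themselves were lower at 1 h, with a median of −0.15 relative to the other times at percentile 0.66 over 11 genes. They were not lower at 1 h than at 2 h, with a median of −0.03 at 2 h over 1 h, at percentile 37.8. At 4 h over 1 h it was 0.17, at percentile 97.85, and at 6 h over 1 h 0.08, at percentile 82.9. Neurod6 read 768, 648, 1263 and 1089, and Wfs1 read 1709, 1637, 2608 and 2205, both lowest at 2 h. Members differed in direction, with 5 above the other times at 1 h and 6 below. Oligodendrocyte and myelin markers had a median of 0.18 at 6 h, at percentile 99.4, with 9 of 11 members above the other times, on the array with Ttr at 4482. This rests in part on the 2 h array, where the list had −0.18 at percentile 1.2 and the actin ratio was 2.70. At 6 h the median was 0.08 over 1 h, at percentile 84.8, and 0.17 over 4 h, at percentile 99.0. Among these markers Qdpr read 5656 at 6 h against 4130, 3720 and 3955, and Mag read 805 against 538, 630 and 484 with a dim second probe set at 110 against 119, 121 and 102, while Mal, at 1218 against 1880, 2017 and 2138, was lower. Blood cell markers, with 4 measured members, were lower at 1 h, with a median of −0.38 relative to the other times at percentile 0.53 and all 4 below. At 6 h over 1 h their median was 0.48 at percentile 99.7, but at 6 h over the other times it was 0.16, within the middle 95% at percentile 91.6. Hba-a1, an alpha globin gene, read 2783 at 1 h and 3413 at 6 h.

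Markers of neurons outside the hippocampus also differed between arrays. Striatal neuron markers had a median of 0.41 at 2 h, at percentile 99.3, from 6 measured genes of which Penk, Pdyn and Tac1 also belong to the neuropeptide list, on the array with the highest ratios of 3' to 5' probe sets, 2.70 for actin and 4.82 for Gapdh. Neocortical neuron markers had a median of −0.25 at 4 h, at percentile 1.11, with Fezf2 at 1375 against 2133, 2158 and 1579. Thalamic neuron markers stayed within the middle 95% of random lists in each comparison, with a median of 0.31 at 2 h over 1 h at percentile 97.2. Markers of CA3 and dentate granule cells (0.18 at 4 h over 2 h, percentile 90.9), interneurons (−0.13 at 6 h over 4 h, percentile 4.17), microglia (−0.11 at 2 h over 1 h, percentile 12.7) and meningeal fibroblasts (−0.12 at 6 h over the other times, percentile 8.24) did so too.

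**Figure D2:**
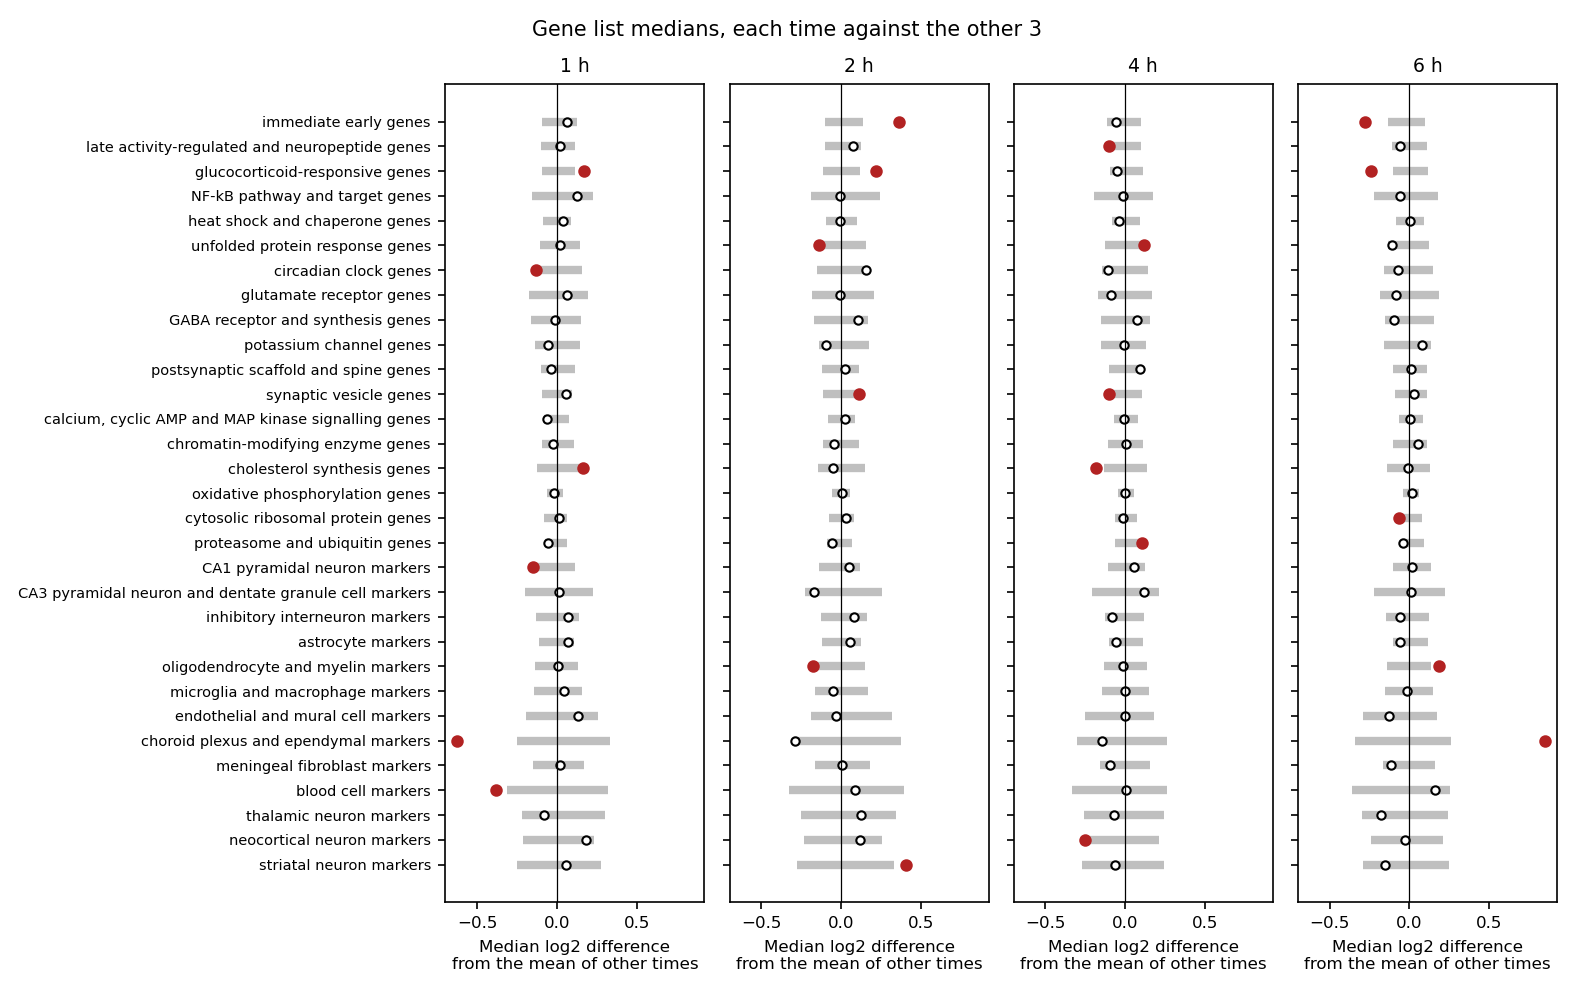
Median log2 difference of each of 31 gene lists at 1, 2, 4 and 6 h from the mean of the other 3 times. Points filled red lie outside the middle 95% of 10000 random lists, and grey bars span the mean of the random lists ± 2 SD. The immediate early genes lie at 0.37 at 2 h and −0.28 at 6 h, and the choroid plexus markers at 0.85 at 6 h.

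Proteasome and ubiquitin genes were slightly higher at 4 h, with a median of 0.10 over the other times at percentile 99.7 and 27 of 35 members above. Genes of the unfolded protein response were higher at 4 h than at 2 h, with a median of 0.20 at percentile 99.7 over 20 genes, of which 12 were higher and 8 lower. Pdia3, a protein disulfide isomerase of the endoplasmic reticulum, read 248 at 2 h and 352 at 4 h, while Pdia4, at 215 and 127, and Creld2, at 283 and 175, were lower at 4 h. By at least 1.5-fold, 1 member was higher and 3 were lower. The 2 h array in this comparison had the highest actin ratio, 2.70. Late activity-regulated and neuropeptide genes were lower at 4 h than at 2 h, with a median of −0.17 at percentile 0.77, and here too the 2 h array had the actin ratio of 2.70. Within that list Inhba, an activin subunit, read 392, 235, 198 and 111 from 1 to 6 h, and Bdnf, the neurotrophin linked to memory, read 3226, 3311, 3808 and 3059.

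Synaptic vesicle genes were lower at 4 h, with a median of −0.10 relative to the other times at percentile 1.42 over 21 genes, 15 of them below. Chromatin-modifying enzyme genes were higher at 6 h, when Ttr stood at 4482, than at 2 h, with its actin ratio of 2.70, by a median of 0.16 at percentile 98.7. Hdac2, a histone deacetylase, read 1076 at 2 h and 1620 at 6 h. Circadian clock genes had a median of −0.13 at 1 h, at percentile 2.03. Dbp, a clock output gene, read 461, 374, 623 and 706, and Per1 read 441, 445, 313 and 385. Cytosolic ribosomal protein genes had a median of −0.06 at 6 h, at percentile 1.67, which was 0.01 after quantile normalization.

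Other lists stayed within the middle 95% of random lists in each comparison. Relative to the other times, their medians at 2 h were 0.01 for oxidative phosphorylation genes, −0.01 for NF-kB pathway genes, −0.01 for heat shock and chaperone genes and −0.01 for glutamate receptors. They were 0.11 for GABA receptor genes, −0.10 for potassium channels, 0.02 for postsynaptic scaffold genes and 0.02 for calcium, cyclic AMP and MAP kinase signalling genes. Single members still differed between arrays. Gabra2, a subunit of the GABA-A receptor, read 1865, 1199, 756 and 926, and the potassium channel gene Kcna1 read 1145, 1576, 2043 and 1634. Rel, an NF-kB subunit, was below the floor on all 4 arrays. Of 310 list medians in 10 comparisons, 53 lay outside the middle 95%, where 15.5 would for lists of genes drawn at random. Lists and comparisons overlap, and related genes can move together between single arrays whatever the reason. The excess is thus no evidence of an effect of time.

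Single genes that stood apart at 1 h included Btf3, a transcription factor subunit, at 2088 against 1093, 1107 and 1105, and Dcn, the matrix proteoglycan decorin, at 5844 against 3395, 2523 and 2915. Ube2s, a ubiquitin-conjugating enzyme, read 637 at 1 h and 274, 213 and 266 later. Lower at 1 h were Cln8, at 211 against 520, 518 and 506, and Tomm20, a mitochondrial import receptor, at 139 against 317, 305 and 386. Csf3r read 199 against 829, 792 and 644, and Tcf7l2 read 121 against 494, 471 and 359. The other probe sets of Csf3r were below the floor on all 4 arrays. The second of Tcf7l2 read 142, 103, 60.1 and 92.4, highest at 1 h, so it went the other way between 1 h and 2 h and was below the floor later. In all, 37 probe sets were higher and 60 lower at 1 h than on each other array by at least 1.5-fold, of 6442 compared, and 27 and 71 after scaling to a common median.

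At 2 h the genes farthest above the others included Dcaf12, at 857 against 368, 273 and 217, Tspan33, at 1123 against 549, 439 and 398, and Tiparp, at 365 against 162, 177 and 110. Farthest below were Pus1, a pseudouridine synthase, at 118 against 635, 576 and 520, and Nbl1, an antagonist of bone morphogenetic proteins, at 136 against 757, 591 and 731. Ccl22 was at least 3.45-fold lower at 2 h than at the other times, where it lay above the floor. The 2 h array held 76 higher and 72 lower probe sets. Scaling to a common median gave 47 and 102, quantile normalization 66 and 96, and a mean intensity of at least 500 gave 7 and 16, so the number of higher ones depended on dim probe sets and on scaling.

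At 4 h, Lct read 582 against 245, 248 and 240, and Epha7, an ephrin receptor, read 1519 against 771, 888 and 943, with its second probe set below the floor on all 4 arrays. Chrna7, the alpha-7 nicotinic receptor, read 147 against 340, 380 and 313, and Tarbp2, a partner of Dicer, read 112 against 296, 413 and 308. The array held 13 higher and 65 lower probe sets, and 24 and 60 after scaling to a common median. At 6 h, besides Igf2, Lbp, the lipopolysaccharide-binding protein, read 417 against 156, 158 and 248. Chka, a choline kinase, read 121 against 302, 531 and 288, and Sh3bp1 read 108 against 373, 277 and 359. Nadk, an NAD kinase, was at least 3.85-fold lower at 6 h than at the other times. The 6 h array held 21 higher and 75 lower probe sets, and 31 and 64 after scaling to a common median.

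**Figure D3:**
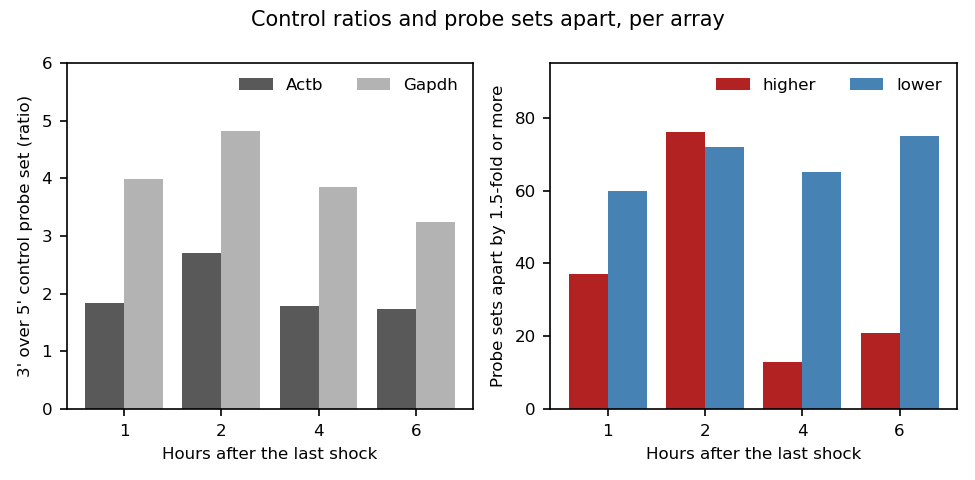
Left, ratio of 3' to 5' control probe sets for Actb and Gapdh on the array of each time, highest at 2 h with 2.70 and 4.82. Right, number of probe sets higher or lower than on each of the other 3 arrays by at least 1.5-fold, with 76 higher at 2 h and 13 at 4 h.

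Genes with lower values at each later time were led by Inhba, 3.53-fold lower at 6 h than at 1 h, Plxna3, a semaphorin receptor, 2.89-fold lower, and Aire, a transcriptional regulator, 2.68-fold lower. Genes with higher values at each later time were led by Kl, 2.87-fold higher, Lbp, 2.68-fold higher, and the integrin subunit Itgb1, 2.34-fold higher, whose second probe set had the same order from 176 to 321. Such courses with a 2-fold span numbered 6 upward and 24 downward, and 15 and 14 after scaling to a common median. Without a size limit there were 251 upward and 313 downward, where 268 of each are expected if the order of the arrays is arbitrary.

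Between pairs of arrays, 84 probe sets were higher and 63 lower at 2 h than at 1 h by at least 2-fold, of 6942 above the floor on both. The order turned to 6 and 8 with the floor at the 60th percentile and to 4 and 8 with a mean intensity of at least 500. At 4 h against 1 h the counts were 38 and 72 of 6886, and 53 and 52 after scaling to a common median. Thyn1 was among the lower, at 530 and 102, but its second probe set went the other way, at 174 and 280. At 6 h against 1 h they were 51 and 63 of 6859, and 63 and 50 after that scaling. At 4 h against 2 h they were 55 and 103, 81 and 64 after scaling to a common median and 71 and 69 after quantile normalization. At 6 h against 2 h they were 64 and 103, and 95 and 70 after scaling to a common median, and at 6 h against 4 h they were 46 and 39. Differences in single probe sets often had no counterpart in a second probe set of the gene. Among 725 genes with a pair of probe sets above the floor, the brighter differed by at least 2-fold 62 times over the 6 pairs of arrays. The second had the same sign in 32 of these, or 51.6%, about the share that unrelated differences would give. The correlation of the log2 differences across these genes, which are not independent replicates, ranged from −0.01 to 0.16, with a mean of 0.079. It was higher in brighter genes, with a mean of 0.18 (0.12 to 0.25) over 393 genes with both probe sets above 250 on all 4 arrays. It was 0.19 (0.08 to 0.29) over 202 genes above 500 and 0.16 (−0.01 to 0.35) over 97 genes above 1000.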

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

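The counts moved with the floor, the fold limit, the minimum intensity and the arrays kept. The probe sets that stood apart were dim, with a median intensity of 255 to 284 against 537 for all compared. Scaling to a common median moved 5 of 22 counts, and moved 23 and reversed 1 of 53 list medians. Quantile normalization moved 1 of 22 counts, and moved 3 and reversed 1 of 53 list medians. The values as deposited moved 0 of 22 counts and 0 of 53 list medians. Counts are given as higher and lower, for 2, 4 and 6 h against 1 h, then for probe sets apart at 1, 2, 4 and 6 h, then for one-way courses. With the floor at the 20th percentile they were 467 and 364, 281 and 366, 283 and 372, then 136 and 219, 271 and 259, 86 and 231, 93 and 279, then 42 and 73. With the floor at the 60th percentile they were 6 and 8, 4 and 12, 8 and 13, then 9 and 13, 14 and 14, 3 and 9, 11 and 15, then 3 and 7. With a 1.5-fold limit the pairs gave 388 and 336, 233 and 367, 258 and 399, and the one-way courses 51 and 104. With a 3-fold limit the pairs gave 13 and 7, 6 and 8, 8 and 3. With a 2-fold limit the probe sets apart were 3 and 10, 11 and 15, 2 and 10, 3 and 6. A mean intensity of at least 500, chosen after the data were seen, gave 4 and 8, 5 and 12, 11 and 9, then 7 and 12, 7 and 16, 3 and 11, 8 and 12. Plain probe sets alone gave 55 higher at 2 h and 33 higher at 6 h than at 1 h. Scaling to a common median gave 47 higher at 2 h and 24 higher at 4 h among those apart, and 15 and 14 one-way courses, of which quantile normalization gave 10 upward. Leaving out 1 array, which leaves fewer arrays to exceed, gave 79 to 92 and 93 to 98 apart at 1 h, 132 to 158 and 111 to 130 at 2 h, 39 to 54 and 104 to 125 at 4 h, and 57 to 62 and 112 to 155 at 6 h. The immediate early median at 2 h was 0.29 with scaling to a common median, 0.30 with the mean over a gene's probe sets and 0.24 without the 6 h array, and at 6 h it was −0.21 with scaling to a common median and −0.17 without the 2 h array. The glucocorticoid median at 6 h over 1 h was −0.16 with scaling to a common median and −0.18 with quantile normalization. The choroid plexus median at 6 h was 0.55 with the floor at the 20th percentile, 0.59 with the floor at the 60th, 0.55 with the mean over a gene's probe sets, 1.39 with the mean over members and 0.55 without Ttr. Medians that changed sign or became 0 were those of the unfolded protein response at 2 h (0.031 with the mean over a gene's probe sets), synaptic vesicle genes at 2 h (−0.029 with the mean over members), ribosomal proteins at 6 h (0.0081 with scaling to a common median and 0.014 with quantile normalization), oligodendrocyte markers at 2 h (0.011 with the mean over a gene's probe sets), choroid plexus markers at 4 h over 1 h (−0.054 with the floor at the 60th percentile, and 0.00, or no difference, without Ttr) and striatal markers at 4 h over 2 h (0.18 with the floor at the 60th percentile). The cause was not tested for these. Of 277 values of named genes, 138 moved with the floor at the 60th percentile, 69 with the mean over a gene's probe sets and 1 with quantile normalization. Among those of at least 1.5-fold in the main setting, 0 changed sign under the settings run. Changes of sign in smaller values were not counted. A gene that no longer stood apart had a gap of 0 and was not counted either, and a higher floor can only shrink a difference. The count of 0 thus says little about how firm the directions are.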

Other observations

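The tests chosen only after the result was seen are those of RNA quality at 2 h, of the medians without the 2 h array, of the glucocorticoid list without shared members, of a 1 h array standing apart, of astrocytes, of endothelial and mural cells, of choroid plexus tissue and of a single failed probe set. The list of heat shock and chaperone genes stayed near 0 as a whole while members differed. Hspa4l, a chaperone gene, read 615, 960, 563 and 495 at 1, 2, 4 and 6 h, and Dnajb4 read 503, 434, 348 and 244, lower at each later time. Among signalling genes Prkca, a protein kinase C, read 284, 408, 540 and 466, and the phosphodiesterase Pde1a read 1015, 946, 738 and 629. Cort, which encodes cortistatin, an interneuron peptide, read 522, 734, 1173 and 896.

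Immediate early genes were highest at 2 h and lowest at 6 h. After quantile normalization the median at 2 h was 0.31, against 0.37 before, still at percentile 100. The random lists were matched on mean expression, so they share an intensity-dependent difference between arrays with or without this step. The test could therefore hardly have come out otherwise and adds no evidence. The distance from matched lists in itself argues against such a difference as the whole cause. For 6 h, the median without the 2 h array stayed at percentile 0.33. Lower RNA quality of the 2 h sample alone thus does not account for the whole difference. The actin and Gapdh ratios fell from 2 h to 1 h, 4 h and 6 h, which is also the order of the list medians. A quality difference graded over all 4 arrays was not tested and stays open. The CA1 pyramidal neuron markers had a median of 0.02 at 6 h, which argues against dilution by RNA of another tissue as the whole cause. Dilution stays open for a part, since the value of 0.02 includes the 1 h array, where those markers were low. At 6 h over 4 h they had −0.07, at percentile 11.3, where the list had −0.14. At 6 h over 1 h they had 0.08 and the list −0.19, and over 2 h −0.04 and −0.42. Lower RNA quality at 2 h stays open for the 2 h value, since the actin ratio was 2.70 there against at most 1.84 elsewhere and 1 array per time cannot separate array from time. The spike-in controls were also highest at 2 h and lowest at 6 h, and their bearing on the list was not tested. A response to the shocks that had passed by 6 h may contribute and was not tested, as no unshocked sample was analysed here.

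Glucocorticoid-responsive genes were lower at 6 h than at 1 h. Without the member shared with the immediate early list, Dusp1, the percentile was 0.06, although removing 1 gene of 25 is a mild test, so it argues only against that member as the whole cause. Without the 1 h array the list at 6 h lay at percentile 0.03 against 2 h and 4 h, a value largely fixed by pairs of arrays already seen and resting in part on the 2 h array with its actin ratio of 2.70. Against 4 h alone, which uses neither array, the median was −0.15 at percentile 0.725, so a 1 h array standing apart does not account for the whole difference but stays open for part of it. The astrocyte markers had a median of −0.12 at 6 h over 1 h, above that of the list by more than 1 SD of random lists. That limit counts the spread of the astrocyte list alone, 0.069, and not that of the glucocorticoid list, 0.064. The lists also share Gjb6 and Glul. The test is thus too lenient to decide, and a lower share of astrocytes stays open. At 6 h over 2 h those markers had a median of −0.17, at percentile 0.985, where the list had −0.38. A lower share of endothelial and mural cells stays open, since those markers had a median of −0.30. Relative to the other times the list medians were 0.17, 0.22, −0.05 and −0.24 at 1, 2, 4 and 6 h. The spike-in controls and the actin and Gapdh ratios had the same order over the arrays, and their bearing on the list was not tested. A decline of the hormone after the shocks is a candidate explanation that was not tested either.

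Transthyretin and other choroid plexus markers were higher at 6 h. Without Ttr the list still lay at percentile 99.88, from 5 members, which is in line with choroid plexus tissue in the 6 h sample. A failed single probe set stays open for part of the pattern, since only 1 of 8 other markers on the array, Folr1, exceeded the other arrays by at least 1.5-fold at 6 h. The choroid plexus borders the hippocampus and may have entered the dissection, but a response of the gene itself in CA1 cannot be told apart from it with 1 array.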
